A study of Mus musculus with 9 samples.

How the data were processed

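Total RNA from whole skin of mice of mixed C57BL, DBA and FVB background, taken 30 days after birth (30 mg of tissue), was pooled per the labels and hybridised to 9 Affymetrix arrays, 3 for control pools (LC) and 2 for each of the transgenic lines L60, L84 and LA. RMA is named in the submitters' processing notes, without a version. The deposited values are a score: every probe set has mean 0 and SD 1 over the 9 arrays (largest row mean 1.9e-07, largest distance of an SD from 1 7.5e-08), with a range of -2.66 to 2.67. Whether the values were on a log scale when they were standardised is not stated. Expression level, fold change and signal over background cannot be recovered from a score, and signal over background sets no limit that could be measured. A difference is therefore in SDs of the gene's probe sets over the arrays. In 44.3% of probe sets some values were tied. Ties within a genotype narrow the residual spread that the test of a gene uses. Examples among the genes named below, by rounded scores, are Chac1, Gprc5d, Hsd3b7, Klf2 and Elp5, equal on both L60 arrays, and Casp4, equal on both L84 arrays. Tagln was equal on LC 2 and LC 3, and Akr1b8 on LC 1 and LC 3. Other named genes may hold ties too. Which calls rest on ties was not tested.

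Of 22690 probe sets, 64 were Affymetrix controls, 20380 named 1 gene, 691 named several and 1555 named none. A gene's score was the mean over the probe sets that name it alone, which gave 12393 genes, 4956 of them with more than 1 probe set. A mean of several standardised probe sets can have an SD below 1. Differences of these 4956 genes are therefore not on quite the same scale as the others. The weight of each probe set in the mean still depends on the standardisation. The GRCm38.p6 gene table served for names, of which 20351 probe sets matched a current record and 0 changed, and for the order of genes along chromosomes.

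The comparisons, gene lists and alternatives were fixed before the data were examined, on the assumption of log2 values with moderated variance and the probe set of highest mean for each gene. That assumption does not hold for scores, and the test was changed because of the unit. Group means were fitted with limma 3.58.1 in R 4.3.3 over all 9 arrays (5 residual degrees of freedom), and each contrast was tested with limma's linear model without variance moderation, whose p does not move when a gene is shifted or rescaled. The contrasts were each line against LC, the lines against each other, the mean of the 3 lines against LC, and an F test over the 4 genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of that contrast. Tested on simulated data, shifts of 5, 10 and 20 residual SDs were recovered for 34%, 98% and 100% of genes with 4 unchanged genes called, and the moderated test recovered 0.

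The 28 gene lists covered hair shaft keratins, hair keratin-associated proteins, the inner root sheath and medulla, hair matrix regulators, bulge and dermal papilla markers, BMP targets, BMP ligands and receptors, the Akt and FOXO and Eda pathways, basal, differentiating and stressed epidermis, sebaceous and cholesterol genes, the cell cycle, melanocytes, muscle, fat, fibroblasts, macrophages, lymphocytes, endothelium, nerve, blood, immediate early genes and sex-linked genes. They were tested with limma's camera on the gene statistics with a preset correlation between genes of 0.01, and again with an estimated correlation. Negative estimates were set to 0. For lists with an estimate of 0 or near 0.01 the second test was therefore laxer than the first or hardly stricter. The members of a list were also adjusted over the list alone. Through a synonym the melanocyte list holds Pard3 in place of Asip, which was planned. In 25 of 168 pairs of a list and a contrast the mean, the median and the test differed in sign, and 0 of these were called.

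The genes named were, for each line against LC, the 10 largest rises and 10 largest falls among called genes whose line arrays all lay on 1 side of all control arrays, without predicted or clone-named genes. Between lines they were the 5 and 5 chosen the same way, and for each list up to 4 called members by size of difference. A fixed set of genes of Akt and BMP signalling, keratins and hair regulators was named whatever its values.

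Alternatives tried were leaving out each array, array weights, replicate number as a block, only the arrays of the 2 groups compared, every probe set on its own and an estimated correlation. Chosen after the data were seen were moderated variance with and without a robust fit, 1 probe set per gene by name, array medians set to 0, leaving out the 3 arrays high in 18S or the 2 arrays with the widest scores, Xist as a covariate, the gene families chosen late without each array and without called members, and BMP targets without members that hair lists share. A filter on dim genes, variance with a trend and cyclic loess need an expression level and were not run. For the chance of the calls, 100 partitions of the arrays were drawn (random seed 20).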

Results

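Gene expression was measured in whole mouse skin taken 30 days after birth, on 9 Affymetrix arrays that each received 1 pool of RNA. The series title concerns mice with a constitutively active form of Akt, a kinase that passes on signals from growth factor receptors, and names impaired bone morphogenetic protein (BMP) signalling. The pools came from controls (LC, n = 3) and from 3 transgenic lines named L60, L84 and LA (n = 2 each). The labels do not say how many mice made up a pool or how the lines differ from each other, so p-values of single genes measure only the spread between these pools. Those of gene lists compare the statistics of the members with those of all other genes. Genes, not pools, act as the replicates there, so a very small p of a list does not measure the spread between pools. The deposited scores were standardised for each probe set over the 9 arrays. A difference is therefore counted in SDs of the gene's probe sets over the arrays. It carries neither a level nor a fold, so a large difference may be a small fold. The number of arrays limits the precision. Probe sets for 18S ribosomal RNA scored higher on LC 1, L60 1 and L84 1 (mean scores 1.13, 2.09 and 0.339) than on the other arrays (-0.642 to -0.528). Spike-in control probe sets averaged 1.28, 1.92 and 0.205 on these 3 arrays, and the 3′ probe sets of Gapdh -1.49, -1.81 and 1.11. For Actb, LC 1 scored 1.31 at the 3′ end and -1.93 at the 5′ end, and L60 1 scored 0.525 and -0.824. Whether the amount or quality of RNA differed on these arrays was not tested. Scores were spread most widely on LA 2 and L84 1, with SDs of 1.31 and 1.2. Over all genes the L84 arrays correlated at -0.296 with each other and the L60 arrays at -0.0228, against 0.229 for the LA arrays, and LC 1 correlated at 0.153 and 0.103 with LC 2 and LC 3, which correlated at 0.604 with each other. Xist, the noncoding RNA of the inactive X chromosome, scored -0.822 to -1.06 on the replicate 1 array of each genotype and 0.077 to 1.48 on the others.

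Akt1 was examined first, because Akt is what the title describes as activated. The mean of its 2 probe sets differed from LC by 0.0947 ± 0.594 (SE) in L60, by 1.22 ± 0.594 in L84 and by -0.617 ± 0.594 in LA. None of these passed limma's test (adjusted p = 1, 0.51 and 0.567). The probe sets had opposite signs in L60 (-0.285 and 0.474) and the same sign with unlike sizes in L84, where 1 of them scored 1.81 and 1.47 against -1.12, -0.329 and -0.242 in LC, a difference of 2.2 ± 0.331 (adjusted p = 0.143 over all probe sets). The other differed by 0.245 ± 0.991 there. A probe set at the 3′ end may lie outside the transcript of a transgene and then checks nothing. Akt2 differed by -0.92, -1.12 and 0.432 in L60, L84 and LA and was not called. In L60 the sign of the Akt1 difference turned without LC 1 (-0.0558) or L60 2 (-0.384) and its size moved without L60 1 (0.573), while in LA it turned without LA 2 (0.221) and reached -1.46 without LA 1.

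The comparison of L60 with LC asked what this line changed in the skin. Hair shaft keratins, the structural filaments of the hair fibre, fell together in L60, with a mean difference of -0.973 ± 0.358 (SD over 12 genes; adjusted p = 5.27e-26, and adjusted p = 1.13e-10 with an estimated correlation). The keratin-associated proteins, which cross-link these filaments, fell by 1.42 ± 0.338 over 25 genes (adjusted p = 3.91e-37, and adjusted p = 0.00136 with an estimated correlation). Genes of the inner root sheath and medulla, the layers that guide and fill the growing shaft, fell by 0.478 ± 0.486 over 17 genes (adjusted p = 2.7e-08, and adjusted p = 0.0252 with an estimated correlation). BMP target genes fell by 0.275 ± 0.718 over 20 genes (adjusted p = 0.00399, and adjusted p = 0.0168 with an estimated correlation), a call lost with limma's moderated variance (adjusted p = 0.0738) and without L84 1 and LA 2, the arrays with the widest scores (adjusted p = 0.0589).

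No member of these lists was called in L60 among all genes. Adjusted over the list alone, 10 of 12 hair shaft keratins, 21 of 25 keratin-associated proteins, 1 of 17 inner root sheath genes and 4 of 20 BMP targets fell. Of single genes, Foxn1, a transcription factor needed for hair keratin expression, differed by -1.58 ± 0.307 (adjusted p = 0.615), and the basal keratins Krt5 and Krt15 by 1.28 ± 0.244 and 0.969 ± 0.179 (adjusted p = 0.606 and 0.591). The BMP targets Id1, Id2 and Id3 differed by -0.083, -0.644 and 0.617. The split by 18S bore on the inner root sheath list: L60 1 minus LC 1, both high in 18S, gave -0.00682, and L60 2 minus the mean of LC 2 and LC 3 gave -0.797. Without L60 2 that list stood at -0.312 (adjusted p = 0.000531), and the BMP targets stood at -0.163 without LC 3 (adjusted p = 0.00502). The same differences were -1.12 and -0.887 for hair shaft keratins and -2.06 and -0.965 for keratin-associated proteins.

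Other lists moved in L60 with the preset correlation alone. Cell cycle genes rose by 0.411 ± 0.291, with 39 of 41 higher (adjusted p = 6.32e-05, but adjusted p = 0.377 with an estimated correlation). Hair matrix regulators, which direct the dividing cells at the base of the follicle, fell by 0.251 (adjusted p = 0.00399, and adjusted p = 0.16 with an estimated correlation), which moderated variance or leaving out the widest arrays also undid (adjusted p = 0.054 and 0.144). Melanocyte genes fell by 0.488 (adjusted p = 7.02e-05, and adjusted p = 0.207 with an estimated correlation). Basal keratinocyte and bulge markers, the latter of the hair follicle's stem cells, were 0.476 and 0.354 higher (adjusted p = 0.00399 and 0.0176, and adjusted p = 0.337 and 0.377 with an estimated correlation). Macrophage and dendritic cell markers were 0.597 higher, fibroblast and matrix genes 0.546 higher and skeletal muscle genes 0.42 lower (a difference of -0.42; adjusted p = 0.000362, 0.0116 and 0.000665, and adjusted p = 0.494, 0.696 and 0.494 with an estimated correlation). Without L60 2 the macrophage difference turned to -0.0775, the fibroblast difference was 0.133 (adjusted p = 0.713) and the hair matrix difference -0.193 (adjusted p = 0.0563). Without L60 1 the muscle difference was -0.0982 (adjusted p = 0.437), and -0.742 without L60 2. Calls that stayed moved to 1.27, 0.959 and -0.314 for the macrophage, fibroblast and melanocyte lists without L60 1, and to -0.389 and 0.317 for the hair matrix and basal keratinocyte lists without LC 1. Lymphocyte and mast cell markers differed by 0.409 (adjusted p = 0.0513) and were called without LC 1 (0.481) and without LA 1 or LA 2 (adjusted p = 0.00717 in each). Epidermal differentiation genes differed by -0.0296 (adjusted p = 0.833), by -0.592 without L60 1 and by 0.533 without L60 2, and were called in either case. The fibroblast call was also lost without LC 2 or LC 3 (0.457 and 0.504), and the bulge call without LC 2, LC 3, L60 1, L60 2, L84 1 or L84 2 (0.279 to 0.429).

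Tested gene by gene, 0 of 12393 genes passed in L60 with limma's unmoderated test and 0 with its moderated variance, while 585 and 465 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.0632. Without L60 2, 5 genes passed. The arrays of L60 and LC did not overlap for 25.1% of genes, where chance gives 20%.

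**Figure D1:**
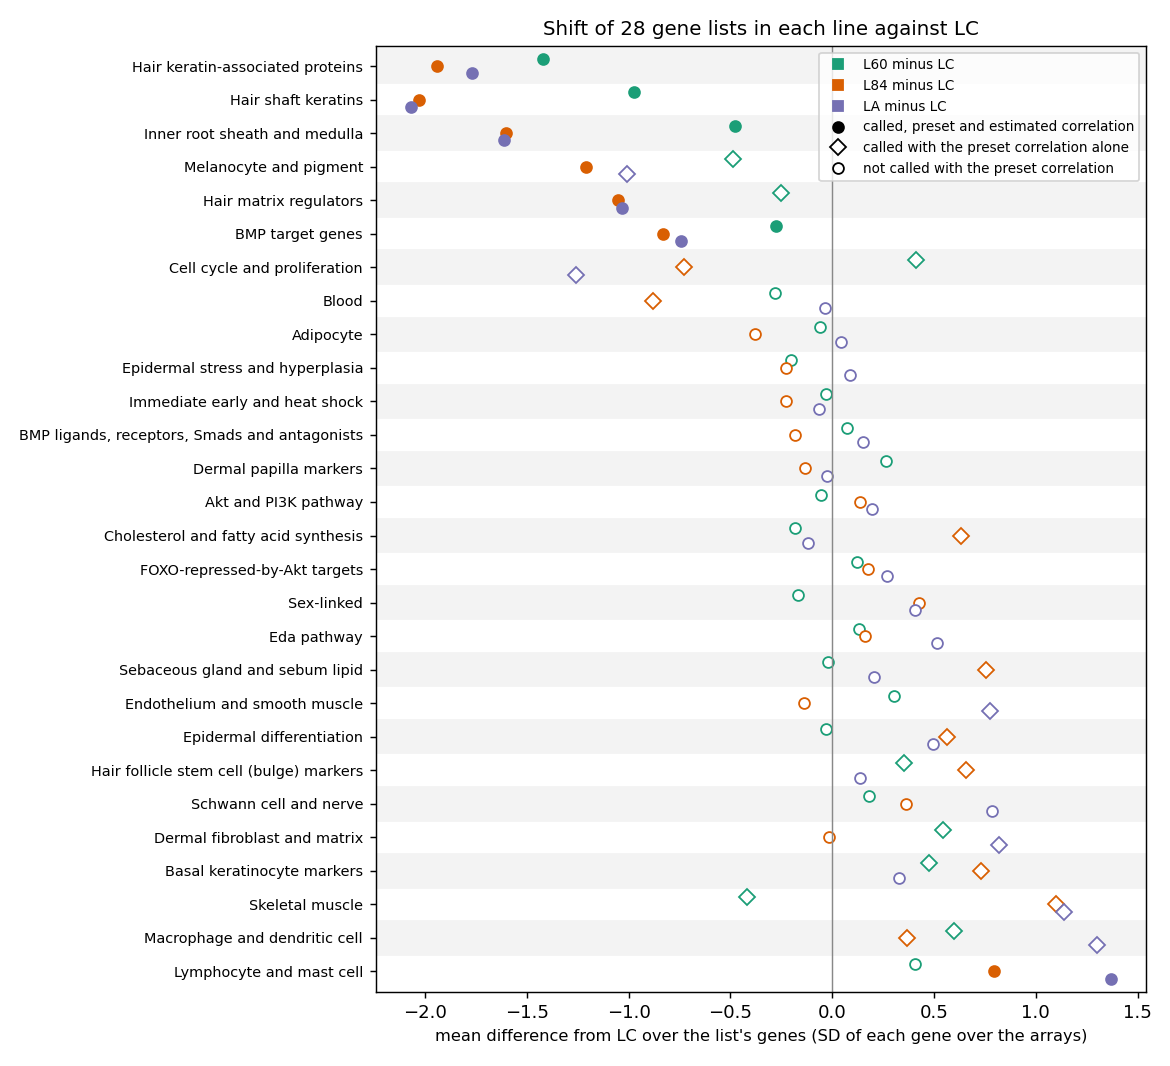
Mean difference from LC over the genes of each of the 28 gene lists (horizontal axis), for L60, L84 and LA (colours). Units are SDs of each gene's probe sets over the arrays. Filled circles mark lists called with the preset and an estimated correlation, open diamonds the preset alone and open circles lists not called. The hair shaft keratins lie at -0.973 in L60, -2.03 in L84 and -2.07 in LA.

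In L84 the hair fibre genes stood lowest against LC. All 12 hair shaft keratins scored lower, by 2.03 ± 0.295 on average (a mean difference of -2.03), and 9 of them fell among all genes tested, 11 adjusted over the list alone (list adjusted p = 5.37e-24, and adjusted p = 7.85e-10 with an estimated correlation). Krt34 differed by -2.23 ± 0.0528 (adjusted p = 0.000718), Krt81 by -2.23, Krt36 by -2.21 and Krt86 by -2.17. Of 25 keratin-associated proteins 7 fell, 22 adjusted over the list alone, with a list mean of -1.94 ± 0.353 (adjusted p = 4.49e-26, and adjusted p = 0.00523 with an estimated correlation). Krtap3-1 differed by -2.29 and Krtap13-1 by -2.14. Genes of the inner root sheath and medulla fell by 1.6 ± 0.696, 6 of 17 one by one and 12 adjusted over the list alone (adjusted p = 1.48e-17, and adjusted p = 0.000114 with an estimated correlation). Among them were S100a3, a calcium-binding protein of the hair cuticle (-1.99 ± 0.0416, adjusted p = 0.000718), Tchh, the trichohyalin of the inner root sheath (-1.97), Padi3, the enzyme that citrullinates it (-2.01), and Krt71 (-1.94).

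BMP target genes fell in L84 by 0.833 ± 1.35 over 20 genes (adjusted p = 1.67e-05, and adjusted p = 7.88e-05 with an estimated correlation). Over all genes 5 of them fell, and adjusted over the list alone 11 fell and 1 rose. They included Dlx2, a homeobox factor (-2.1), Smad6, an inhibitor within the BMP pathway (-1.98, adjusted p = 0.0398), Bambi, a decoy receptor (-1.96 ± 0.107, adjusted p = 0.00797), and Hoxc13, a homeobox factor of hair (-1.88). Id1, Id2 and Id3, commonly read as BMP responses, differed by -0.565, -0.139 and -1.52 and were not called (adjusted p = 0.799, 0.967 and 0.172). BMP ligands, receptors and antagonists as a list differed by -0.181 (adjusted p = 0.487), and within it Bmp4 differed by -2.14 (adjusted p = 0.162). Hair matrix regulators fell by 1.05 ± 0.984, 3 of 29 one by one and 10 adjusted over the list alone (adjusted p = 5.96e-09, and adjusted p = 0.00029 with an estimated correlation), with Hoxc13, Msx2 (-1.85) and Elf5 (-1.65) called and Foxn1 at -2.26 (adjusted p = 0.0856) and Lef1 at -1.86 (adjusted p = 0.195) not called.

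The melanocyte list, pigment genes except for Pard3, fell in L84 by 1.21 ± 0.895 over 18 genes (adjusted p = 4.7e-08, and adjusted p = 0.0443 with an estimated correlation), 2 of them called and 10 adjusted over the list alone. Tyrp1 differed by -1.91 and Dct by -1.35, both enzymes of melanin synthesis. Lymphocyte and mast cell markers rose by 0.793 ± 0.804 with 0 of 27 genes called, 0 adjusted over the list alone (adjusted p = 0.000142, and adjusted p = 6.68e-05 with an estimated correlation); without L84 2 the rise was 0.703 (adjusted p = 0.071). Single genes that rose included Il33, an alarm cytokine of epithelia (2.47, adjusted p = 0.0409), the protease Adam8 (2.37), Krt15 (2.28), Akr1b8 (2.23), Krt5 (2.21), the phospholipase Plcg2 (2.14), Irf9, a mediator of interferon signals (2.01), Gas1 (1.99), Krt77 (1.89) and the amino acid transporter Slc6a20a (2.45). Single genes that fell outside the lists included Hp (-2.45), Cybrd1 (-2.34), Chac1 (-2.31), Gprc5d, a receptor found in hair-forming cells (-2.25), and Slc25a37 (-2.19).

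Further lists passed in L84 with the preset correlation alone. Cell cycle genes fell by 0.728 ± 0.615 (adjusted p = 4.17e-08, but adjusted p = 0.18 with an estimated correlation), 0 of 41 called and 2 adjusted over the list alone, and with both of the most widely spread arrays left out the difference was -0.248 (adjusted p = 0.103), the same as without L84 1 alone (adjusted p = 0.0277), while without L84 2 it was -1.21. Basal keratinocyte markers rose by 0.732 with 2 of 19 called, bulge markers by 0.655 with 2 of 23 called, epidermal differentiation genes by 0.566 with 1 of 31 called and skeletal muscle genes by 1.1 with 0 of 34 called; with an estimated correlation these had adjusted p = 0.236, 0.18, 0.461 and 0.18. Sebaceous, cholesterol and macrophage lists were 0.755, 0.634 and 0.366 higher and blood genes differed by -0.881 (adjusted p = 0.00597, 0.00405, 0.00891 and 0.0486, and adjusted p = 0.441, 0.448, 0.557 and 0.0822 with an estimated correlation). Adjusted over the list alone, 7 basal keratinocyte markers rose and 1 fell, 5 bulge markers rose, 6 epidermal differentiation genes rose and 2 fell, and 1 sebaceous gene rose and 1 fell. Without L84 1 the cholesterol difference turned to -0.0633, the fibroblast list went from -0.015 to 0.982 (adjusted p = 1.27e-06), and the bulge, epidermal and sebaceous lists were no longer called (0.477, 0.204 and 0.245). Basal keratinocyte, muscle and macrophage calls stayed there, at 0.405, 0.493 and 1.01. Without L84 2 the macrophage difference turned to -0.277 and the fibroblast list stood at -1.01, and the muscle, epidermal differentiation, sebaceous and cholesterol lists rose further (1.71, 0.929, 1.27 and 1.33). The blood call was lost without any of LC 1, L60 1, L60 2, L84 1, L84 2, LA 1 and LA 2 (-1.02 to -0.741).

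With limma's moderated variance 0 genes passed in L84, where 1559 had an unadjusted p under 0.05 and the smallest adjusted p was 0.3. In simulated standardised scores that test recovered 0 changed genes. The simulation changed a small share of genes, so it cannot tell whether the 0 in L84 comes from the test alone. Without moderation 1513 genes had an unadjusted p under 0.05 and 70 passed, 20 higher and 50 lower. The count was 5 without LC 2, 19 without LC 3, 28 without LA 1 or LA 2, 31 without L84 1, 40 without L60 1 or L60 2 and 129 without L84 2, where the split turned to 71 higher and 58 lower. Without both of the most widely spread arrays it was 25 higher and 26 lower. Arrays of L84 and LC did not overlap for 28.5% of genes, where chance gives 20%. The falls of the hair shaft, keratin-associated and inner root sheath lists held both among the arrays low in 18S (-1.98, -1.59 and -1.87) and between L84 1 and LC 1 (-2.14, -2.49 and -1.18).

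**Figure D2:**
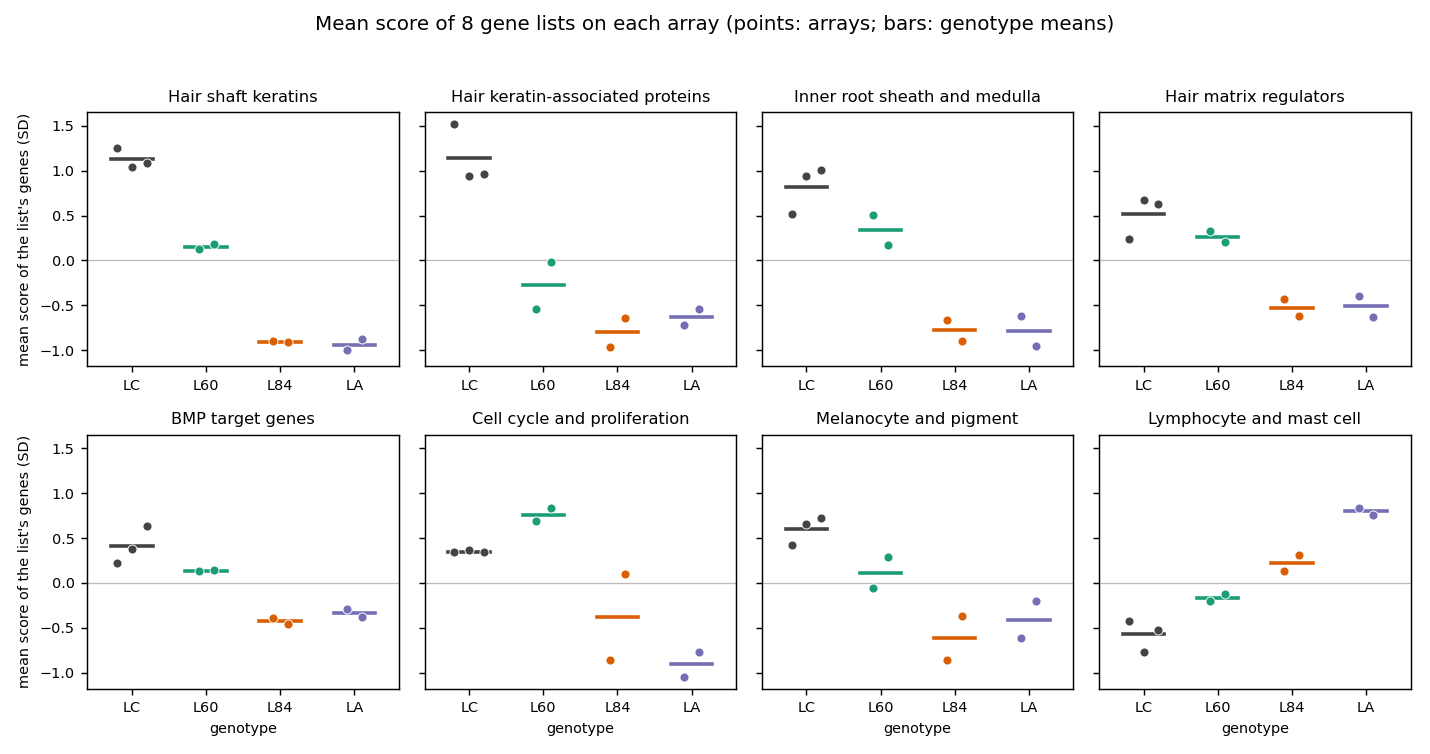
Mean score of the genes of 8 lists (vertical axis, in SD) on each array (points), by genotype (horizontal axis), with bars for genotype means. For hair shaft keratins the LC arrays sit between 1.04 and 1.25, the L60 arrays at 0.129 and 0.179, and the L84 and LA arrays between -1 and -0.878.

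LA showed the same hair lists low against LC. Hair shaft keratins fell by 2.07 ± 0.0908, 9 of 12 one by one and 12 adjusted over the list alone (adjusted p = 1.96e-18, and adjusted p = 1.69e-07 with an estimated correlation), among them Krt86 (-2.13 ± 0.0897, adjusted p = 0.00399) and Krt33b (-2.16). Keratin-associated proteins fell by 1.77 ± 0.678, 8 of 25 one by one and 22 adjusted over the list alone (adjusted p = 1.96e-18, and adjusted p = 0.0308 with an estimated correlation), with Krtap9-3 at -2.13. Genes of the inner root sheath and medulla fell by 1.61 ± 0.651, 8 of 17 one by one and 12 adjusted over the list alone (adjusted p = 1.35e-13, and adjusted p = 0.00113 with an estimated correlation), with S100a3 at -2.05 ± 0.0416 (adjusted p = 0.000812). Hair matrix regulators fell by 1.03 ± 1.09 (adjusted p = 5.88e-07, and adjusted p = 0.00234 with an estimated correlation), 3 of 29 one by one (Hoxc13 and Msx2, both -2.09, and Elf5, -2.05), and adjusted over the list alone 10 fell and 1 rose. Among the arrays low in 18S, which include both LA arrays, the first 3 of these differences were -2, -1.58 and -1.76.

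BMP target genes fell in LA by 0.743 ± 1.59 (adjusted p = 0.000141, and adjusted p = 0.000742 with an estimated correlation). Over all genes 5 of 20 fell and 1 rose, and adjusted over the list alone 11 fell and 3 rose. Smad6 differed by -2.25, Bambi by -2.12 (adjusted p = 0.00472) and Dlx2 by -2.12, while Tgfbi, a secreted matrix protein, was 2.4 higher. Id1, Id2 and Id3 differed by -1.97, -0.62 and -1.53 (adjusted p = 0.198, 0.609 and 0.0849). BMP ligands, receptors and antagonists differed by 0.152 (adjusted p = 0.927), with Bmp4 at -0.889 and the antagonist Nog at 1.78 (adjusted p = 0.287 and 0.237).

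Lymphocyte and mast cell markers rose in LA by 1.37 ± 0.696, with 26 of 27 genes higher, 0 called over all genes and 2 adjusted over the list alone (adjusted p = 2.06e-05, and adjusted p = 4.38e-06 with an estimated correlation). In L84 and LA alike the estimated correlation of this list was 0, below the preset 0.01, so the second test was the laxer one. Macrophage and dendritic cell markers rose by 1.3 ± 0.873 (adjusted p = 5.11e-05, but adjusted p = 0.497 with an estimated correlation); 2 of 31 rose and 1 fell, against 8 and 1 adjusted over the list alone. Cd207, the langerin of Langerhans cells, was 2.49 higher (adjusted p = 0.00472) and Cd74, the invariant chain of MHC class II, 2.45 higher, whereas the class II gene H2-Eb1 was lower (-1.8, adjusted p = 0.0202). Cell cycle genes fell by 1.26 ± 0.879, 7 of 41 one by one and 21 adjusted over the list alone (adjusted p = 3.84e-13, but adjusted p = 0.0648 with an estimated correlation), including Mki67, a marker of dividing cells (-2.13, adjusted p = 0.0176), Mcm2 (-1.99), Cenpa (-1.97) and Cdc20 (-1.9). Pigment genes fell by 1.01 ± 1.18, 3 of 18 one by one and 5 adjusted over the list alone (adjusted p = 5.88e-05, but adjusted p = 0.165 with an estimated correlation), namely Dct (-2.34), Pmel (-2.29) and Tyrp1 (-2).

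Skeletal muscle, fibroblast and endothelial lists were 1.14, 0.818 and 0.776 higher in LA with the preset correlation (adjusted p = 2.06e-05, 0.0332 and 0.0246), which gave adjusted p = 0.444, 0.921 and 0.165 with an estimated correlation. Adjusted over the list alone, 0 muscle genes passed, 1 fibroblast gene rose and 1 fell, and 2 endothelial genes rose. Over all genes Tnc, tenascin C, fell in the fibroblast list (-1.81). The fibroblast call was lost without LC 2, LC 3 or LA 1 (0.728, 0.775 and 0.635) and the endothelial call without LC 2 or LA 1 (0.667 and 0.54). Basal keratinocyte and epidermal differentiation lists did not pass (0.326 and 0.493, adjusted p = 0.444 and 0.146), though 2 and 3 of their members rose, 4 and 5 adjusted over the list alone with 1 falling in each. These were Krt5 (1.99) and Krt15 (1.93), and Krt77 (2.35), Dmkn (2.22) and Krt10 (2.11). Bulge markers differed by 0.138 (adjusted p = 0.908), by -0.141 without LA 1 and by 0.417 without LA 2, with Krt15 higher and Sfrp1, a Wnt antagonist, lower (-1.75), and adjusted over the list alone 7 rose and 3 fell. Among the sebaceous, cholesterol and blood lists the differences were 0.205, -0.119 and -0.034 (adjusted p = 0.875, 0.632 and 0.857).

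The 10 largest rises in LA by the naming rule were those of Il1r2, a decoy receptor for interleukin 1 (2.52, adjusted p = 0.0112), Rnase4 and Tnxb (both 2.52), Elovl2 (2.51), Hsd3b7 and Tmem150a (both 2.5), Cd207, Myf6 and Sult1a1 (each 2.49) and Akap12 (2.46). The 10 largest falls were those of Eef1e1 (-2.49, adjusted p = 0.023), Elp5 and Mrpl36 (both -2.48), Mt4, a metallothionein of stratified epithelium (-2.45), Lap3 (-2.43), Sesn3, a target of FOXO factors (-2.42), Mrps12 (-2.4), Gar1 and Hmgn5 (both -2.38) and Tmem53 (-2.35). With limma's moderated variance 0 genes passed in LA, where 3223 had an unadjusted p under 0.05 and the smallest adjusted p was 0.115. Without moderation 2576 had an unadjusted p under 0.05 and 223 passed, 101 higher and 122 lower. With every array's median set to 0 the split was 89 higher and 142 lower. The count was 40 without LA 2, 45 without LC 2, 51 without LC 3 and 97 without LC 1, L60 1 or L60 2. The split turned to 112 higher and 73 lower without LA 1, to 155 and 151 without L84 1 or L84 2 and to 27 and 18 without both of the most widely spread arrays. Arrays of LA and LC did not overlap for 48.8% of genes, where chance gives 20%.

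The remaining 10 lists were called in no line. Akt and PI3K pathway genes differed by -0.0539, 0.139 and 0.196 in L60, L84 and LA. The list of FOXO target genes differed by 0.121, 0.178 and 0.268, with Klf2 higher (2.18) and Sesn3 lower in LA. That list also holds Ccnd1 and Ccnd2, and its members need not respond to Akt in 1 direction, so its mean is no reading of Akt activity. Differences in the same order were 0.263, -0.133 and -0.0248 for dermal papilla markers, 0.132, 0.16 and 0.513 for the Eda pathway and -0.2, -0.228 and 0.0881 for epidermal stress genes, which were called in L60 without LC 1 (-0.362, adjusted p = 0.00798). Gjb2, a gap junction protein of that last list, was lower in L84 (-1.77, adjusted p = 0.00848) and LA (-2.09). They were -0.0598, -0.38 and 0.0431 for adipocyte genes, 0.18, 0.362 and 0.784 for Schwann cell and nerve genes, with Mbp, myelin basic protein, higher in LA (1.78), and -0.0313, -0.229 and -0.066 for immediate early genes. Sex-linked genes differed by -0.17, 0.425 and 0.408. The last is the BMP ligand list given above, at 0.0716 in L60.

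Several genes fixed for naming were not called in any line. The basal keratin Krt14 differed by 1.2, 1.57 and 0.13 in L60, L84 and LA, the stress keratins Krt6a and Krt17 by -0.846, -0.676 and -1.39 and by -0.062, -1.23 and 0.035, and the bulge marker Cd34 by 0.81, 1.35 and 2.19. Differences were 0.771, -0.934 and -0.255 for Shh, -1.08, -0.309 and 0.542 for Edar, -0.246, -1.28 and -1.25 for the receptor Bmpr1a, -0.886, 0.513 and -0.91 for Bmp2, and -1.07, -1.16 and -0.688 for Bmp7. Scd1, a desaturase of sebaceous glands, differed by -0.0919, 1.65 and 0.0998, and Ccnd1 by 0.416, -1.52 and -1.64.

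The lines were then compared with each other, which is also the test of whether their differences from LC differed. L84 stood below L60 in hair shaft keratins (-1.06, adjusted p = 4.97e-17, and adjusted p = 4.92e-07 with an estimated correlation), in the inner root sheath list (-1.12), in hair matrix regulators (-0.794), in BMP targets (-0.558) and in cell cycle genes (-1.14, adjusted p = 9.91e-16, and adjusted p = 0.0371 with an estimated correlation), and above it in skeletal muscle (1.52) and lymphocyte genes (0.385). LA stood below L60 in hair shaft keratins (-1.09), the inner root sheath list (-1.13), hair matrix regulators (-0.78), BMP targets (-0.469) and cell cycle genes (-1.67), and above it in lymphocyte genes (0.959). These 13 of the 32 calls among the lists held with an estimated correlation. That estimate was 0 for lymphocyte genes and 0.0135 for BMP targets, against the preset 0.01, so it hardly made the test stricter there. Calls with the preset correlation alone included skeletal muscle in LA against L60 (1.56). LA against L84 had such calls for cell cycle (-0.529), bulge (-0.517), basal keratinocyte (-0.406), sebaceous (-0.551), cholesterol (-0.753), macrophage (0.93), fibroblast (0.833) and endothelial genes (0.916). Keratin-associated proteins differed by -0.524 between L84 and L60 and by -0.349 between LA and L60, and lost their calls (adjusted p = 0.31 and 0.613 with an estimated correlation). They differed by -0.258 and -0.0826 without L60 2, the latter not called (adjusted p = 0.0634), by -0.79 and -0.615 without L60 1, and the call against LA was also lost with moderated variance (adjusted p = 0.154). Without L84 1 the cell cycle and muscle differences of L84 from L60 were -0.659 and 0.913, still called. Without L84 2 the lymphocyte difference of L84 from L60 was 0.294 (adjusted p = 0.27), and without LA 1 the BMP target difference of LA from L60 was -0.513 (adjusted p = 0.0508).

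By gene, 14 passed between L84 and L60, 2 higher and 12 lower. The lower genes included Tagln, a smooth muscle protein (-2.74), Bambi (-1.49) and Gjb2 (-1.63). Hair genes among them were Krt25 (-1.81, adjusted p = 0.00376), Krt27 (-1.74), Tchh (-1.71), Krt35 (-1.69), S100a3 (-1.64), Krt31 (-1.52), Krt33a (-1.44) and Krt34 (-1.14). Nt5c2 (1.25) and Plcg2 (2.23) were higher. Between LA and L60 78 genes passed, 21 higher and 57 lower. Those lower included Upf1 (-2.77), Utp20 (-2.74), the replication genes Pola1 and Rpa3 (both -2.72), Lsm3 (-2.72), Mcm6 (-2.58), Mcm4 (-2.54), Mki67 (-2.51), Mcm2 (-2.47), Krt25 (-1.82), Krt35 (-1.78), Hoxc13 (-1.77) and Bambi (-1.65). Those higher included Slc37a1 (2.58), Pla2g2d (2.51), Sag (2.36), Casp4 (2.29), Ace (2.26), Cd207 (2.04), Klf2 (1.98) and Krt77 (1.16). Between LA and L84 2 genes passed, Slc37a1, higher in LA (2.23, adjusted p = 0.0341), and D17H6S56E-5, lower in LA (-2.27, adjusted p = 0.0164), the latter named after its values were seen. Slc37a1 scored -0.152 on all 3 LC arrays, a tie that narrows the spread used by its test.

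All 3 counts were 0 with limma's moderated variance, and 995, 2002 and 1317 genes had an unadjusted p under 0.05. Groups did not overlap for 29.4%, 50.4% and 33.5% of genes, where chance gives 33.3%. Without single arrays the count between L84 and L60 was 3 to 9, except without L84 2 (15, of which 9 higher): LC 1 gave 8, LC 2 3, LC 3 4, L60 1 9, L60 2 5, L84 1 9 (5 higher), and LA 1 or LA 2 7. For LA against L60 it was 13, 4 and 11 without LC 1, LC 2 and LC 3, 8 and 5 without L60 1 and L60 2 and 15 without LA 2. For LA against L84 it was 0 without LC 1 or LC 2, 1 without L60 1 or L60 2 and 131 without L84 2.

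Across genotypes, 91 genes passed limma's F test (1839 at an unadjusted p under 0.05; 0 with moderated variance). The largest sets had their highest mean in LC and their lowest in LA (31 genes) or in L84 (18 genes), followed by highest in L60 and lowest in LA (14 genes) and highest in LA and lowest in LC (13 genes). The mean of the 3 lines differed from LC for 79 genes, 22 higher and 57 lower (1654 at an unadjusted p under 0.05; 0 with moderated variance), and the arrays of lines and LC did not overlap for 6.67% of genes, where chance gives 2.38%. For that mean, hair shaft keratins differed by -1.69, keratin-associated proteins by -1.71, inner root sheath genes by -1.23 and BMP targets by -0.617 (adjusted p = 6.71e-25, 1.03e-28, 9.89e-18 and 1.09e-05, and adjusted p = 3.28e-10, 0.00291, 0.000103 and 4.65e-05 with an estimated correlation). Without LC 1, LC 2 and LC 3 the F test called 10, 6 and 8 genes, without L60 1 and L60 2 36 and 30, without L84 2 188 and without LA 1 and LA 2 24 and 21. The contrast of the mean called 50, 13 and 23 genes without LC 1, LC 2 and LC 3, 37 and 40 without L60 1 and L60 2 and 37 and 34 without LA 1 and LA 2.

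L84 and LA shared 64 called genes, of which 49 were lower and 15 higher than LC in both, hair keratins among the former. Independent lists of these sizes would share 0.492 lower and 0.163 higher genes, and unchanged lines set against the same simulated controls shared 0.04. No gene was changed in that simulation and its genes varied independently, so hardly any could be called. Its shared count therefore cannot gauge how far the shared controls raise the overlap of called genes. The differences of the lines from LC correlated at 0.531 over genes, which are not independent replicates, against 0.399 in that simulation (covariance 0.59 against 0.222), and 68.6% of genes had the same sign against 63.1%. For L60 the correlation with L84 was 0.447 (covariance 0.292) and with LA 0.314 (covariance 0.257), against 0.4 (covariance 0.222) in both simulations. The 3 control pools could not be split into a pair of sets of 2, so part of the excess may come from the shared controls. In L60, 59 of the 64 shared genes had a mean within the range spanned by the means of LC, L84 and LA. That range does not require L60 to lie between LC and both lines: Elf5 averaged -0.57 in L60 and -0.431 in L84. The genes were picked because LC lay apart from both lines, so the count is no independent sign of an intermediate L60. No gene was called in all 3 lines, 0 with moderated variance too, since L60 had none, and 5 were without L60 2. The count of 64 was 5 without LC 2, 19 without LC 3, 21 without LA 2, 24 without L84 1, 26 without LA 1 and 37 without L60 1 or L60 2.

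**Figure D3:**
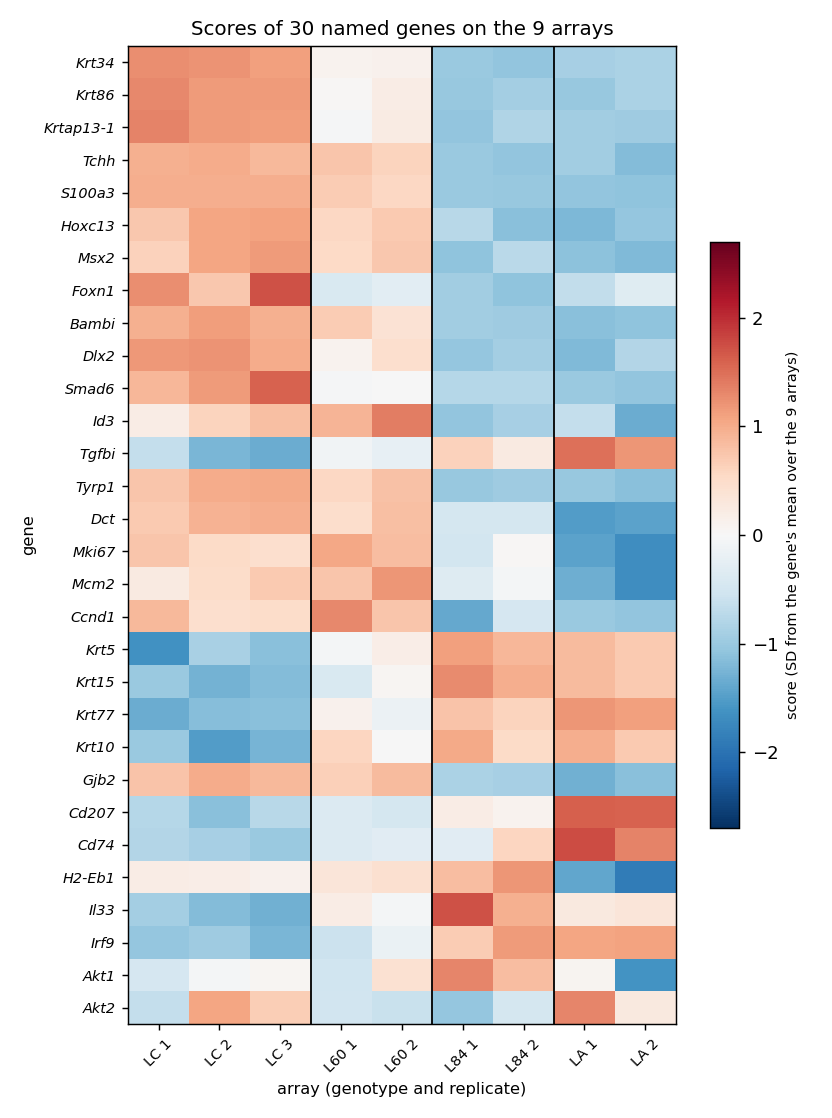
Scores of 30 named genes (vertical axis) on the 9 arrays (horizontal axis, genotype and replicate), with red above and blue below the gene's mean. Units are SDs of the gene's probe sets over the arrays. S100a3 averages 0.976 in LC, -1.01 in L84 and -1.07 in LA, and Cd207 averages -0.881 in LC and 1.61 in LA.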

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

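The tests of a deviating array, of the 18S split and of less active follicles were chosen after the results were seen. The lists below were tested for a difference between lines, and those given passed with the preset and with an estimated correlation. For BMP targets and lymphocyte markers, with estimates of 0.0135 and 0, the second test was hardly stricter or was laxer. Against L60, L84 stood lower in hair shaft keratins (-1.06), the inner root sheath and medulla (-1.12), hair matrix regulators (-0.794), BMP targets (-0.558) and cell cycle genes (-1.14), and higher in skeletal muscle (1.52) and lymphocyte and mast cell markers (0.385). LA stood lower than L60 in hair shaft keratins (-1.09), the inner root sheath and medulla (-1.13), hair matrix regulators (-0.78), BMP targets (-0.469) and cell cycle genes (-1.67), and higher in lymphocyte and mast cell markers (0.959). The cell cycle and muscle lists had opposite signs against LC in L60 and in both other lines. Without L84 1 the cell cycle and muscle differences of L84 from L60 were -0.659 and 0.913. The lymphocyte call in L84 was lost without L84 2 (0.294, adjusted p = 0.27) and the BMP target call in LA without LA 1 (-0.513, adjusted p = 0.0508).

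By gene, 14 differed between L84 and L60, 78 between LA and L60 and 2 between LA and L84. Without LC 1, LC 2 and LC 3 the first count was 8, 3 and 4, the second 13, 4 and 11 and the third 0, 0 and 3. Without L60 1 and L60 2 they were 9 and 5, 8 and 5, and 1 and 1. The first was also 9 without L84 1 and 7 without LA 1 or LA 2, the second 15 without LA 2 and the third 131 without L84 2. Of the named genes with opposite signs against LC in the lines compared, Plcg2 (2.23) was higher and Tagln (-2.74) lower in L84 than in L60. Genes of DNA replication and division were lower in LA than in L60, namely Pola1 (-2.72), Rpa3 (-2.72), Mcm6 (-2.58), Mcm4 (-2.54), Mki67 (-2.51) and Mcm2 (-2.47). So were the RNA processing genes Upf1 (-2.77), Utp20 (-2.74) and Lsm3 (-2.72), the Wnt antagonist Sfrp1 (-1.91) and H2-Eb1 (-2.02). Slc37a1 (2.58), Pla2g2d (2.51), Sag (2.36), Casp4 (2.29) and Ace (2.26) were higher in LA than in L60, and Slc37a1 was also higher in LA than in L84 (2.23). Among probe sets that name no gene or several, which the comparisons by gene leave out, 2 were called in L84 and 23 in LA against LC. No genotype had the 4 arrays that the rule for a sample lying outside its own group needs.

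Hair shaft keratins, keratin-associated proteins and inner root sheath genes were lower in L84 and LA than in LC. A single array as the cause was argued against by the fits without each array in turn, where the least negative of the differences was -1.44 (without LA 2). The split of the arrays by 18S was argued against by differences of -1.18 or lower within arrays of like 18S score. Fewer or less active hair-forming follicles in the sampled skin may account for the pattern, since hair matrix and cell cycle genes were lower too, by at least the -0.728 of the cell cycle list in L84, although the cell cycle call was kept in neither line (adjusted p = 0.18 in L84 and 0.0648 in LA with an estimated correlation) and the L84 difference was -0.248 without L84 1. Whether the transgene, the age at which a hair cycle phase was reached or the piece of skin sampled led to this was not tested and stays open.

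Chance was tested for 2 counts with 100 partitions of the 9 arrays into groups of the same sizes. It was unlikely for both but is not excluded by so few partitions. The mean of the lines against LC called 79 genes in the real partition, which 1 partition reached, the real one, and the highest other called 14. The test over the 4 genotypes called 91 genes, again reached by 1 partition, with 17 as the highest other. Without LC 2, a fit with fewer arrays than these partitions, the real grouping called 13 and 6 genes.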

How the results depend on the processing

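The variance model, the probe set by name, array medians at 0, the sets of arrays left out together and the Xist covariate were chosen after the data were seen, and the other alternatives before. Values below are in the order L60, L84 and LA against LC, L84 against L60, LA against L60 and LA against L84, unless named. Except where a cause is given, the cause was not tested.

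The hair shaft, keratin-associated and inner root sheath lists kept their calls against LC in all 3 lines in every fit without 1 array, and so did the BMP target and hair matrix lists in L84 and LA. Of 140 calls of named genes, fits without 1 array kept 21 (without LC 2) to 99 (without L84 2), each with 4 residual degrees of freedom. Where a line was left with 1 array, that array was assumed to vary like the other groups, which supplied the spread. Leaving out each array gave 0 to 5, 5 to 129, 40 to 306, 3 to 15, 4 to 112 and 0 to 131 genes, 13 to 110 for the mean of the lines, 6 to 188 for any genotype, 0 to 5 in all 3 lines and 5 to 57 in both L84 and LA. It gave 9 to 14, 12 to 16 and 10 to 12 lists against LC and 23 to 34 between lines. Akt1 ranged from -0.384 to 0.573 in L60, from 0.983 to 1.47 in L84 and from -1.46 to 0.221 in LA.

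Moderated variance called 0 genes in every comparison, plain or robust: L84, LA, L84 against L60, LA against L60, LA against L84, the mean of the lines, any genotype and both L84 and LA (0 in each). On simulated scores it recovered 0 changed genes. Only a small share of genes was changed there, so the simulation cannot tell whether these counts of 0 come from the test alone. Moderated variance kept 62 of the list calls. An estimated correlation left 4, 7 and 6 lists against LC and 13 between lines. The replicate number as a block, which leaves 3 residual degrees of freedom, gave 1, 3, 1, 0, 1 and 1 genes, 1 for the mean, 1 for any genotype, 1 in all lines and 1 in both L84 and LA. Xist was low on each replicate 1 array. Eif2s3y, a Y-linked gene, was higher on replicate 1 in LC (0.803 against -0.167 and -0.134), L60 (1.08 against -1.97) and L84 (1.35 against -0.618). In LA it hardly differed (-0.157 against -0.188). The labels give the arrays only a shared number. Of 12 pairs with the same number, 5 had residual correlations over 0.1 (range -0.0833 to 0.345). Not every array correlated best with its own number, since L60 2 reached 0.127 with LC 3 and at most 0.115 with its own. Residuals of a line's 2 arrays are exact opposites, so values between lines repeat. The pairs therefore cannot decide whether the number marks a batch or sex. Only the arrays of the 2 groups compared, a fit with fewer arrays, gave 4, 19, 38, 0, 3 and 0 genes. Array weights gave 9, 19, 245, 4, 42 and 0 genes, 235 for the mean, 8 in all lines and 19 in both L84 and LA, and -0.000851 for Akt1 in L60; 183 of the LA genes were the same.

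Every probe set tested on its own gave 0 between LA and L84 and kept the other counts within 1.5 times. The probe set by name gave 0 there too and -0.285 for Akt1 in L60, the value of that probe set alone (-0.285), and kept 118 named calls. Array medians at 0 gave 7 between L84 and L60 and kept 128. Xist as a covariate gave 3, 18 and 0 genes between the lines and 19 for any genotype, with 4 residual degrees of freedom.

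Without the 3 arrays high in 18S, 2 residual degrees of freedom were left, and the counts were 11, 12, 1 and, for LA against L60 and L84, 13 and 9, with 11 for the mean, 11 for any genotype and 1 in both L84 and LA; 2 of the L84 genes and 0 of the LA genes were the same. Without the 2 arrays with the widest scores (3 residual degrees of freedom), the counts were 4, 51, 45, 40, 23 and 23, with 33 for the mean, 42 for any genotype, 16 in both L84 and LA, 10 lists in L84 and 0.221 for Akt1 in LA. Most called genes were then higher for L84 against L60 (22), LA against L60 (14) and the mean (17).

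Sign changes are given here only for list differences called in the main fit or in the fit named, and lists called in neither are left out. Without the arrays high in 18S, those that changed sign were cholesterol (-0.0512) and fibroblast (1.11) in L84 against LC, basal keratinocyte in L84 against L60 (-0.0153) and fibroblast in LA against L84 (-0.164). Without the widest arrays they were cholesterol (-0.0633) and fibroblast (0.982) in L84 against LC, basal keratinocyte (-0.0713), fibroblast (0.436) and macrophage (0.413) in L84 against L60, and basal keratinocyte (0.229), sebaceous (0.0484) and cholesterol (0.244) in LA against L84. With single arrays left out, the lowest and highest values in L60 against LC were -0.592 and 0.533 (without L60 1 and without L60 2) for epidermal differentiation and -0.0775 and 1.27 (without L60 2 and without L60 1) for macrophage. In L84 against LC, without L84 1 or L84 2, they were -0.0633 and 1.33 for cholesterol, -1.01 and 0.982 for fibroblast and -0.277 and 1.01 for macrophage. In L84 against L60 they were -0.0713 and 0.583 for basal keratinocyte and -1.56 and 0.436 for fibroblast, again without L84 1 or L84 2, and -0.904 and 0.444 for macrophage (without L60 1 and without L60 2), which was 0.413 without L84 1. In LA against L84 they were -0.164 and 1.83 for fibroblast and -0.572 and 0.65 for muscle, without L84 1 or L84 2.

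A filter on dim genes, variance with a trend and cyclic loess could not be run on scores, and signal over background, which limits arrays, is not in the files.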

Other observations

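The gene families of antigen presentation and of the ribosome, the H2-Eb1 tests and the test of growth stage in L60 were chosen after the results were seen, and the test of BMP targets outside the hair lists was written before its result. Genes of MHC class I presentation, which display peptides on the cell surface, were 0.818 ± 0.96 higher in L84 (adjusted p = 4.99e-06, and adjusted p = 0.000168 with an estimated correlation) and 1.56 ± 0.615 higher in LA (adjusted p = 1.89e-08, and adjusted p = 3.86e-06 with an estimated correlation), with 2 and 3 of 21 genes called. In LA these included H2-K1 (2.19, adjusted p = 0.00494) and B2m (2.17), while H2-D1, another member, differed by 0.548 and was not called (adjusted p = 0.252). Many members are H2 genes. Whether another H2 haplotype, raised below for H2-Eb1, bears on their scores was not tested. Without the members called in any line the other 18 were 0.681 and 1.48 higher (adjusted p = 0.0357 and 0.00189 with an estimated correlation). In L60 the 21 genes differed by 0.263 and were not called (adjusted p = 0.0848, and adjusted p = 0.331 with an estimated correlation), and by 0.151 without L60 2. Genes of MHC class II presentation were 1.59 ± 1.36 higher in LA, with 9 of 10 higher, 1 called higher and 1 called lower, and the list was not called with an estimated correlation (adjusted p = 0.000284, but adjusted p = 0.0564 with an estimated correlation). In L84 they were 0.732 higher with 9 of 10 higher and 0 called (adjusted p = 0.000133, and adjusted p = 0.0495 with an estimated correlation), and 0.404 higher without L84 2. Without the called members Cd74 and H2-Eb1, of which the latter was lower in LA, the estimated correlation gave adjusted p = 0.11 in L84 and 0.0139 in LA. Ribosome biogenesis genes fell by 0.819 in L84 and by 1.22 in LA as a list, with 0 and 3 of 52 genes called (adjusted p = 1.84e-08 and 7.58e-12, and adjusted p = 0.00559 and 0.000584 with an estimated correlation), and the 49 others still differed by -0.808 and -1.18 (adjusted p = 0.0244 and 0.00189 with an estimated correlation). Cytosolic ribosomal proteins fell by 1.17 in LA (adjusted p = 3.41e-10, and adjusted p = 0.0351 with an estimated correlation), with 0 of 47 genes called, and by 0.771 without LA 2. Mitochondrial ribosomal proteins and proteasome subunits differed in LA by -1.03 and -1.01 and were not called with an estimated correlation (adjusted p = 0.0924 and 0.216), and without LA 2 they differed by -0.63 and -0.585. Each of these differences in L84 and LA kept its sign with array medians set to 0.

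BMP targets were lower in L84 and LA than in LC, and 8 of the 20 are also on a hair list, so that a loss of hair cells could lower the list without a change in BMP signalling. The 12 members that no hair list holds differed by -0.704 ± 1.46 in L84 and by -0.527 ± 1.91 in LA. Id1 and Id3 are among them. In each of these lines 8 of the 12 were lower, and 3 were called lower, namely Bambi, Dlx2 and Smad6. The 12 members passed limma's camera test in both lines, with the preset and with an estimated correlation. The latter gave the smaller p, so it was no stricter a check. The result argues against the shared members as the whole cause in L84 and LA. It leans on Bambi, Dlx2 and Smad6, at -1.96, -2.1 and -1.98 in L84 and -2.12, -2.12 and -2.25 in LA. Whether the set shifts without these 3 was not tested, so a wider fall of BMP targets outside the hair lists is not shown. In L60 these 12 members differed by -0.175, with 7 of 12 lower and 0 called, and passed with an estimated correlation but not with the preset one. Hair cells may still express some of these genes, which stays open, and Tgfbi was higher in LA (2.4).

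H2-Eb1 was lower in LA while other MHC class II genes were higher, and the other E chain gene, H2-Ea, did not rise with them (0.24, adjusted p = 0.62). The 27 macrophage and dendritic cell markers outside class II and without Cd74 were higher in LA by 1.3 on average (27 of 27 higher, and 1.08 to 1.52 without each array in turn). These values give no sign of fewer antigen-presenting cells. They are no independent test, since the list they come from had already been seen to be higher in LA. The whole list did not pass camera with an estimated correlation (adjusted p = 0.497). Another H2 haplotype in the LA mice, whose background is mixed, may account for it and cannot be told apart from regulation with these files. Among the neighbours of H2-Eb1 on its chromosome, with H2 genes and the 2 genes that prompted the test left out, the share called in LA was 1.26 times that of other genes (4 of 180; Fisher's exact test, one-sided, p = 0.396), and with these 2 genes kept it was 1.87 times (6 of 182; p = 0.108 by the same exact test), which neither bears out nor excludes a haplotype. Between LA and L84 both called genes, Slc37a1 and D17H6S56E-5, were such neighbours, which is what prompted the test.

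In L60 the shaft lists were lower than in LC without a lower cell cycle list, while hair matrix regulators fell by 0.251 with the preset correlation alone (adjusted p = 0.00399, and adjusted p = 0.16 with an estimated correlation). An earlier stage of hair growth may account for it: keratin-associated proteins, made late in the shaft, reached 76.5% of their mean difference in L84 and LA, and the inner root sheath list 29.8%, a gap of 46.7 percentage points, with hair shaft keratins at 47.5% and hair matrix regulators at 24.2%. The gap was 22 to 71.4 points without each array in turn, but among arrays low in 18S the shares were 60.9% and 43.9%, a gap of 17 points, below that range. The 18S split may therefore account for part of the gap, other technical explanations were not tested, and the hypothesis, formed on the data that tested it, stays open.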
